A study of Rattus norvegicus with 6 samples.

How the data were processed

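Total RNA of magnetically sorted dermal blood endothelial cells from 6 rats was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The deposited values were taken as log2 expression per probeset, which rests on the RMA entry of the labels and on their range. They reach 19.93, higher than scanned intensities usually give on that scale, so the unit of every difference depends on this reading. They were made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes; the versions, the probeset library and any genome build are not given in the sources used here. RMA corrects background, makes the distributions of the arrays alike and summarises the probes of a probeset. The values have 2 decimals, nearly equal quartiles in the 6 columns and a ceiling between 19.70 and 19.93 per array, with 31 to 59 probesets within 0.05 of an array's maximum. A difference in a gene near that ceiling can be hidden; 39 genes lay within 0.5 of it. They were used as deposited, with no further scaling.

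The table holds 24834 probesets, of which 1646 are controls. Of the 23188 others, 15049 have 1 gene symbol in the platform annotation given, 0 have several and 8139 are unnamed here. All 15049 Entrez identifiers were found in the RefSeq table of assembly GRCr8, and 0 symbols changed. The 15037 symbols were tested as genes; for the 10 with over 1 probeset the probeset with the highest mean was kept. Genes with a mean under the 25th percentile of all probesets (3.52) were left out as dim, which left 11515 genes and removed 3522. Probesets without a name were tested only in the alternative that takes each probeset on its own, where 0 of 5774 were called and 143 had an unadjusted p under 0.05.

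The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Knockout was compared with wildtype in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, on all 6 arrays and with genotype alone in the design, since each group holds 2 females and 1 male. Adjusted p-values are Benjamini-Hochberg values from limma, two-sided, with a threshold of 0.05. Sex was tested beside genotype, and the interaction in a model with both. An exact permutation test of 3 against 3 cannot give a p under 0.1, so none is reported. The gene lists (11 of cell type markers, 15 of pathways and 1 of Y-linked and X-inactivation genes) were tested with camera at an inter-gene correlation of 0.01, adjusted over the 26 lists with at least 5 members tested; camera with an estimated correlation and fry were alternatives. The genes within 2 Mb of Il33 were taken by their start and end positions in GRCr8, and no coordinates are reported here.

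Il33 is always named, with every gene that passed. As fewer than 24 passed, the 12 genes with the smallest p in each direction are named as not passed, if the groups did not overlap and the difference was at least 0.5. From each list the members called and the 3 with the highest mean are named, and for sex the 6 genes with the smallest p. Genes with predicted names only were passed over; 1 gene was passed over in this way. A list mean is the mean over its tested members.

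Alternatives were no filter on dim genes, a filter at the 50th percentile, quantile normalization again, centring on array medians, sex as a covariate, females only, eBayes with trend and robust options, array weights, each probeset on its own, the mean of a gene's probesets, an unmoderated statistic, other thresholds, windows of 1 and 5 Mb, and leaving out each array in turn. For the lists, the trend and the array weights entered camera, which has no robust option. Chosen after seeing the data were the keratinocyte marker median as a covariate, the spike-in mean as a covariate, high or low spike-in signal as a block (above or below the midpoint of the range of the array means), the lists without genes near the ceiling or without Il33, and the neighbours of Il33 without each array and without the filter.

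The scripts were tested on simulated data with the means and spreads of the 11515 genes. With 200 genes changed, 0% were recovered at a log2 difference of 1, 42.7% at 2, 94.1% at 4 and 99.1% at 6. A single gene lowered by 6 among unchanged genes was recovered in 70% of simulations. With independent genes camera recovered the proliferation list shifted by 0.5 in 100% of simulations, and called 6 lists in all over 20 simulations without effect.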

Results

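Gene expression was measured with Affymetrix arrays in blood vessel endothelial cells of abdominal rat skin, from 3 Il33 knockout animals (28, 27 and 52) and 3 wildtype animals (34, 45 and 37) of the Sprague-Dawley strain. Each group held 2 females and 1 male (52 and 37). The skin had been digested with collagenase, the suspension depleted of CD45-positive leukocytes and Lyve-1-positive lymphatic endothelium, and CD31-positive cells retained. Each array came from an animal of its own, so the limma p-values of single genes rest on the spread between these animals. Camera p-values at the preset correlation of 0.01 compare the genes of a list with the other genes. They take the members as nearly independent, so they do not measure the spread of a list between animals. The median log2 expression of all probesets was 4.63 to 4.78 per array and the highest value 19.70 to 19.93. The number of arrays limits the precision, with a median standard error of 0.387 on the log2 scale for a difference between genotypes.

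Markers of blood endothelium gave high signal in every array. Plvap, a protein of endothelial fenestrae, and Cdh5, the adhesion molecule of endothelial junctions, had means of 19.79 and 19.67 in the knockout and 19.77 and 19.66 in the wildtype, within 0.5 of the highest value an array gave, so a difference in either gene could not show. The median of the blood endothelial list lay at the 96.7th to 97.4th percentile of all genes. Markers of other skin cells were also measured, and they varied between animals of the same genotype. The median of the keratinocyte list was 11.54 in wildtype 34, 9.09 in wildtype 45 and 6.31 in wildtype 37, against 8.93, 7.47 and 7.39 in knockout 28, 27 and 52. Lymphatic markers had medians of 8.55 to 9.69 in the females and of 7.27 and 5.90 in the males. Leukocyte markers had medians at the 22.4th to 46.2nd percentile of all genes.

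**Figure D1:**
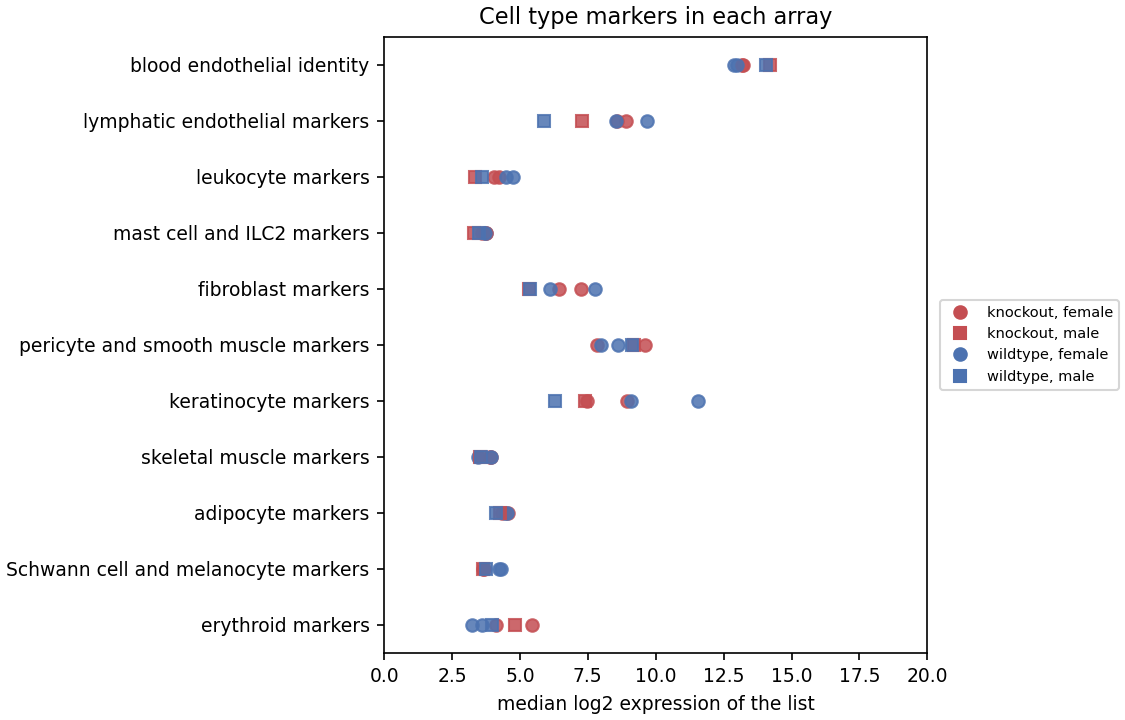
Median log2 expression of each cell type marker list in each array (horizontal axis), with knockout arrays in red, wildtype arrays in blue, females as circles and males as squares. The blood endothelial medians lie between 12.87 and 14.20, and the keratinocyte medians range from 6.31 to 11.54.

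Genotype was not the leading difference among the arrays. The split between genotypes held 15.4% and that between sexes 38.3% of the sum of squares over the genes tested. Any split of 6 arrays into 2 groups holds a share by chance, so neither share alone shows an effect. The male arrays 52 and 37 were the most similar pair, with Pearson's r = 0.990 across genes, which are not independent replicates. The 8 bacterial and phage control transcripts, which are added during preparation and hold no rat RNA, had means of 10.26, 10.42 and 10.12 on arrays 28, 34 and 45 and of 9.33, 8.82 and 8.91 on arrays 27, 52 and 37. This split holds 1 knockout and 2 wildtype arrays on the high side, so its effect was examined beside the comparison of genotypes for Il33, for the number of genes called and for the gene lists. Scores on the leading principal component (45.3% of the variance) followed nearly the order of these controls.

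**Figure D2:**
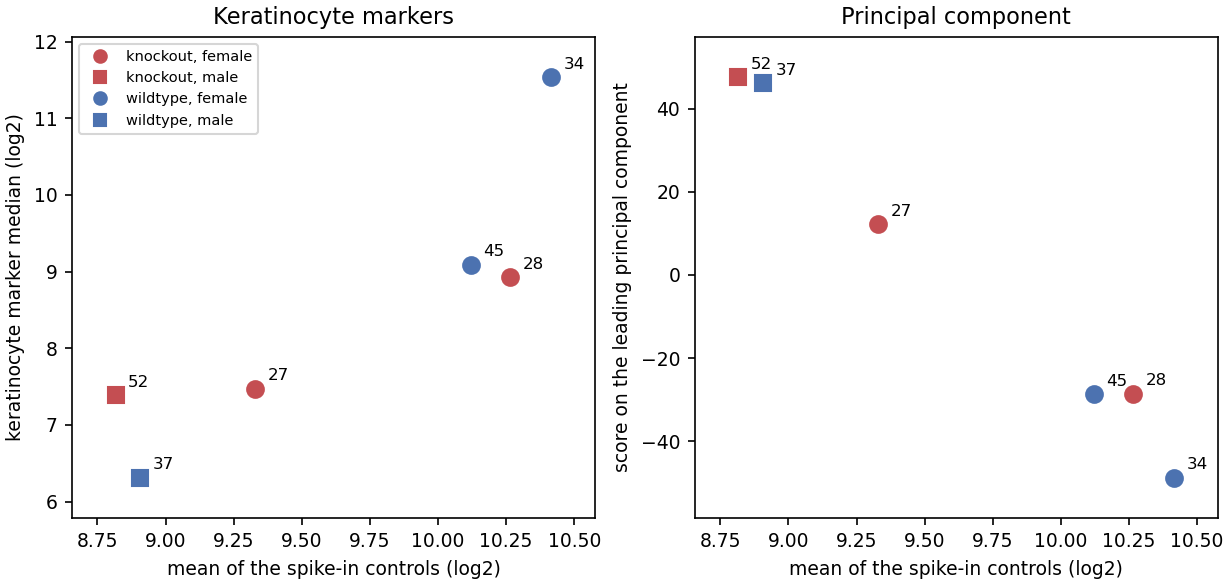
Keratinocyte marker median (log2, left) and score on the leading principal component (right) against the mean of the spike-in controls (log2) in each array, with animal numbers beside the points. Arrays 28, 34 and 45, with spike-in means of 10.12 to 10.42, had keratinocyte medians of 8.93 to 11.54, and arrays 27, 52 and 37 had medians of 6.31 to 7.47.

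The comparison of genotypes asks what loss of interleukin-33, a nuclear cytokine of barrier cells that is released on damage, does to the transcriptome of these endothelial cells. Il33 itself (probeset TC0100003458.rn.2) fell by 6.84 on the log2 scale in the knockout (SE 0.73, 95% interval -8.47 to -5.21). Its limma p was 3.81e-06 unadjusted and 0.0439 adjusted over all genes tested. Its values were 8.07, 8.37 and 9.82 in knockout 28, 27 and 52 and 13.86, 16.32 and 16.60 in wildtype 34, 45 and 37. The group means were 8.75 ± 0.94 and 15.59 ± 1.51 (SD, n = 3 each). All 3 wildtype arrays lay above all 3 knockout arrays, and the difference was -6.87 in the females and -6.78 in the males. It was -7.02 among the arrays with high spike-in signal and -7.51 among those with low signal. The signal left in the knockout lay at the 79.5th to 87.1st percentile of all genes. Where the deletion lies relative to the probes is not given in the sources used here, so the residual signal does not show whether a shortened transcript was present. The difference kept its direction under all 19 alternatives, but its p adjusted over all genes ranged from 1.98e-04 to 0.661 and passed 0.05 in 10 of them. The lowest came with the keratinocyte median as a covariate, a setting chosen after seeing the data. The call was lost on leaving out knockout 28 (adjusted p = 0.270), 27 (0.661) or 52 (0.0687), or wildtype 45 (0.653) or 37 (0.0773).

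**Figure D3:**
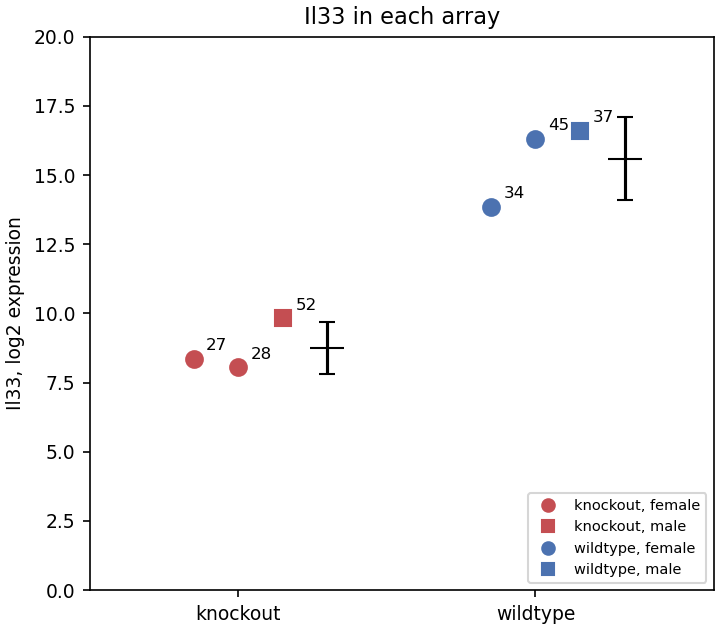
Log2 expression of Il33 in each array (vertical axis) by genotype, with females as circles, males as squares and animal numbers beside the points; the black bars give the mean and SD of each group of 3. The knockout arrays lie between 8.07 and 9.82 and the wildtype arrays between 13.86 and 16.60.

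Apart from Il33, none of the 11515 genes tested passed the test between knockout and wildtype. The genes with the smallest p values that were higher in all 3 knockout arrays than in all 3 wildtype arrays, as genes that did not pass, included Plat, the tissue plasminogen activator (13.86 ± 1.16 against 11.87 ± 0.09), Klf9 (14.42 ± 0.20 against 13.04 ± 0.66), Cited2 (8.57 ± 0.30 against 7.19 ± 0.67) and Psme4, a proteasome activator (9.50 ± 0.32 against 8.06 ± 0.52). Pgf, the placental growth factor, differed by 1.20, Plcb4 by 1.0, Tcim by 1.14, Mapk6 by 1.09, Rnf144a by 1.26, Slfn9 by 1.26, Rad18 by 1.18 and Atp1b2 by 1.31. The genes lower in every knockout array that did not pass included Fdps, an enzyme of isoprenoid synthesis (6.45 ± 0.34 against 7.64 ± 0.64), Ndufb4 of respiratory complex I (8.58 ± 0.41 against 9.76 ± 0.54) and Mrps23 of the mitochondrial ribosome (6.50 ± 0.65 against 7.67 ± 0.11). Nap1l2 differed by -1.27, Pde6d by -1.17, Or5p72 by -1.53, Dok1 by -1.01, Emg1 by -1.15, Omd by -1.06, Dtwd1 by -1.49, Fam221b by -1.15 and Trpm5 by -1.10. Some of these genes lay near the background probesets, whose medians were 4.55 to 4.73 per array. Or5p72 was 3.31 against 4.84, Nap1l2 3.41 against 4.68 and Dok1 3.18 against 4.19. Trpm5 was 3.34 against 4.44 and Fam221b 3.76 against 4.91. Among the higher genes Rad18 was 4.70 against 3.52. Differences so near background may not reflect expression in these cells.

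After Il33 the smallest adjusted p was 0.999 (limma). At an unadjusted p under 0.05 there were 227 genes, 133 higher and 94 lower in the knockout, where 5% of the genes tested would be 576. The groups did not overlap for 720 genes, or 6.25%, where chance gives 10% for 3 against 3. With sex as a covariate 473 genes, and with high or low spike-in signal as a block 320 genes, had an unadjusted p under 0.05, and Il33 was again the only gene called in each. In simulated data of this design with 200 genes changed at once, 42.7% of genes changed by 2 on the log2 scale were recovered and 0% of those changed by 1. A single gene lowered by 6 among unchanged genes was recovered in 70% of simulations. Small effects, and larger ones confined to single genes, could thus go undetected with these arrays.

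Of 26 gene lists, 13 differed between genotypes by camera with a preset correlation, 9 of them higher in the knockout and 4 lower, and 0 with an estimated correlation or by fry. In 25 of the 26 lists no member was called, either over all genes or adjusted over the list alone; the exception is Il33 in its own list. Erythroid genes had the largest mean difference. All 6 tested members were higher on average in the knockout, by a mean of 1.46 (camera adjusted p = 0.00119; adjusted p = 0.496 with an estimated correlation). The alpha-globin Hba-a1 was 16.25 ± 1.78 against 14.16 ± 2.55 and Hbb 12.28 ± 2.25 against 10.60 ± 1.64, while Hba-a3 differed by 2.06. Knockout 28 alone had a list mean of 11.54, against 6.87 to 9.07 in the other arrays, and without it the mean difference was 0.47 (camera adjusted p = 0.332). The mean was 0.85 without wildtype 45 and 2.21 without knockout 27, both called. Each of the 13 lists lost its call on leaving out at least 1 array.

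Inflammatory genes that respond to NF-kB were higher in the knockout for 22 of 25 members, by a mean of 0.58 (camera adjusted p = 0.00119; adjusted p = 0.496 with an estimated correlation). The chemokine Ccl2 was 19.13 ± 0.76 against 18.23 ± 1.96, Il6 17.60 ± 0.54 against 16.73 ± 1.15, and the inhibitor Nfkbia 18.79 ± 0.11 against 18.28 ± 0.65. The lowest values of Ccl2, Il6 and Nfkbia were all in wildtype 34 (15.98, 15.44 and 17.54), the array with the highest keratinocyte median. Without that array the list mean was 0.082 and the camera adjusted p was 0.514, while it was 0.90 without knockout 28 and 0.98 without wildtype 37. Immediate early and heat shock genes, which cell dissociation induces, were higher for 26 of 29 members by a mean of 0.36 (camera adjusted p = 0.00187; adjusted p = 0.496 with an estimated correlation). Its members of highest signal Hspa8, Dusp1 and Egr1 had differences of 0.027, 0.037 and 0.050 at the ceiling of the arrays, and the list differed by -0.17 in the male pair. The list mean was 0.18 without wildtype 45 (camera adjusted p = 0.117), 0.26 without knockout 28 (0.193) and 0.62 without wildtype 37.

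Of the lists of endothelial genes, those of blood endothelial identity, Notch and arterial genes, tip cells and fatty acid handling passed camera with the preset correlation, and those of venous, junction and shear responsive genes did not. Lists share members: 9 of 25 blood endothelial, 4 of 23 Notch, 7 of 18 tip cell and 2 of 13 fatty acid genes tested were also in another list. Dll4, Cxcr4 and Unc5b, for example, were in both the Notch and the tip cell list. The calls are therefore not independent findings. For blood endothelial identity 20 of 25 members were higher, with a mean of 0.32 (camera adjusted p = 0.00866; adjusted p = 0.496 with an estimated correlation), and Eng, a receptor of the TGF-beta family, was 18.89 ± 0.13 against 18.59 ± 0.23. This list had a camera adjusted p of 0.0620 without wildtype 34 and of 0.111 without knockout 28, and a mean of 0.48 without wildtype 37. Notch and arterial genes were higher for 17 of 23 members by a mean of 0.32 (camera adjusted p = 0.0139; adjusted p = 0.496 with an estimated correlation). Efnb2, an arterial ephrin, was 12.47 ± 0.62 against 11.53 ± 0.54, Epas1 differed by 0.48 and Hes1 by 0.31. The list mean was 0.13 without wildtype 45 (camera adjusted p = 0.298), 0.25 without knockout 28 (0.196) and -0.064 in the male pair. Angiogenic tip cell genes had a mean of 0.35 over 18 members, 12 of them higher (camera adjusted p = 0.0222; adjusted p = 0.496 with an estimated correlation), with differences of 0.82 for Mcam, 0.74 for Pdgfb and 1.09 for Angpt2. That mean was 0.14 without wildtype 45 (camera adjusted p = 0.298), and the call was lost too without knockout 28 (0.281) or wildtype 37 (0.0581). Fatty acid handling genes had a mean of 0.37, with 10 of 13 members higher (camera adjusted p = 0.0431; adjusted p = 0.496 with an estimated correlation). In that list Angptl4, an inhibitor of lipoprotein lipase, was 16.39 ± 0.26 against 15.24 ± 1.14, Meox2 differed by 0.11, and Fabp4, at 19.74 against 19.71, lay at the ceiling. The call was lost without knockout 28 (camera adjusted p = 0.419), wildtype 37 (0.118) or wildtype 45 (0.0902). The list means of the tip cell and fatty acid genes were higher in all 3 knockout arrays than in all 3 wildtype arrays, and those of the other 11 called lists overlapped. For the tip cell genes the lowest knockout mean was 7.769 (knockout 52) and the highest wildtype mean 7.766 (wildtype 34). For the fatty acid genes these were 10.827 (knockout 27) and 10.738 (wildtype 37). Of the 26 lists tested 3 did not overlap, where chance gives 10% for 3 against 3.

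Lists of pericyte and of lymphatic markers passed camera with the preset correlation, each with a mean above 0 that depended on single animals. Pericyte and smooth muscle markers had a mean of 0.47 over 16 members, 12 of them higher (camera adjusted p = 0.00826; adjusted p = 0.496 with an estimated correlation), with Rgs5 at 18.59 ± 0.08 against 17.77 ± 1.13, Pdgfrb at 13.27 ± 0.30 against 12.15 ± 0.86 and Des differing by 0.27. In the male pair that list differed by -0.27, and its mean was 0.15 without wildtype 45 (camera adjusted p = 0.25), 0.29 without knockout 27 (0.145) and 0.89 without wildtype 37. Lymphatic markers had a mean of 0.53, with 9 of 11 members higher (camera adjusted p = 0.0357; adjusted p = 0.496 with an estimated correlation). The mean rested on wildtype 37, whose list mean was 8.19 against 9.42 to 10.31 in the other arrays; without it the mean was -0.048 (camera adjusted p = 0.642). The mean was 0.31 without knockout 27 (0.235), 0.52 without knockout 28 (0.155) and 0.88 without wildtype 45, where the list was called. Ccl21, the lymphatic chemokine, differed by 1.87, Fgl2 by 0.38 and Gja1 by 0.30 between genotypes.

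The lists lower in the knockout by camera with the preset correlation were those of keratinocyte, fibroblast, leukocyte and proliferation genes. Keratinocyte markers were lower for 11 of 13 members by a mean of -1.21 (camera adjusted p = 0.00119; adjusted p = 0.514 with an estimated correlation), with the basal keratin Krt15 at 11.24 ± 2.75 against 13.99 ± 4.40, Krt1 at 12.17 ± 2.60 against 13.52 ± 3.54 and Perp differing by -2.02. The keratinocyte difference was -2.00 in the females and 0.38 in the male pair, and that of the proliferation list -0.51 and 0.0091, so neither was lower in the males. Fibroblast markers had a mean of -0.38, with 12 of 16 lower (camera adjusted p = 0.0172; adjusted p = 0.496 with an estimated correlation), with differences of -0.71 for the collagen Col3a1, -0.46 for Dcn and -0.69 for Fbn1. Leukocyte markers had a mean of -0.26, with 14 of 18 lower (camera adjusted p = 0.0222; adjusted p = 0.514 with an estimated correlation), although Cd68 differed by 0.46, Lcp1 by -0.10 and Lyz2 by -0.42. Proliferation genes had a mean of -0.34, with 16 of 22 lower (camera adjusted p = 0.00130; adjusted p = 0.496 with an estimated correlation), while Pcna, its member of highest signal, differed by 0.30, Tyms by -0.46 and Mcm2 by 0.54. Without wildtype 34, which had the highest values of all 4 lists, none of them was called, and the means of the keratinocyte, fibroblast and leukocyte lists became -0.028, 0.20 and 0.082 and that of the proliferation list -0.19. Without knockout 52 the keratinocyte, fibroblast and leukocyte calls were lost as well, with means of -0.82, -0.15 and -0.069, and without wildtype 37 the means were -2.38, -0.71 and -0.53. Without knockout 28 they were -1.94, -0.66 and -0.41, all called, and without wildtype 45 the fibroblast mean was -0.64 and the leukocyte call was lost (camera adjusted p = 0.0590).

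With high or low spike-in signal as a block, camera with the preset correlation called 8 of the 13 lists, all in the same direction. They were the blood endothelial, lymphatic, erythroid, Notch and arterial, tip cell, immediate early, fatty acid and proliferation lists. The keratinocyte list then had a mean of -0.25, the fibroblast list -0.081, the leukocyte list -0.053, the pericyte list 0.15 and the NF-kB list 0.21. The block leaves knockout 28 as the only knockout of high signal and wildtype 37 as the only wildtype of low signal. The erythroid and lymphatic means, which depended on those animals, became 1.79 and 0.82 with the block, against 1.46 and 0.53 without it. The 8 calls thus do not show that these lists are free of the technical split. Of the 13 lists, 8 had the same sign in the male pair as over all animals.

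**Figure D4:**
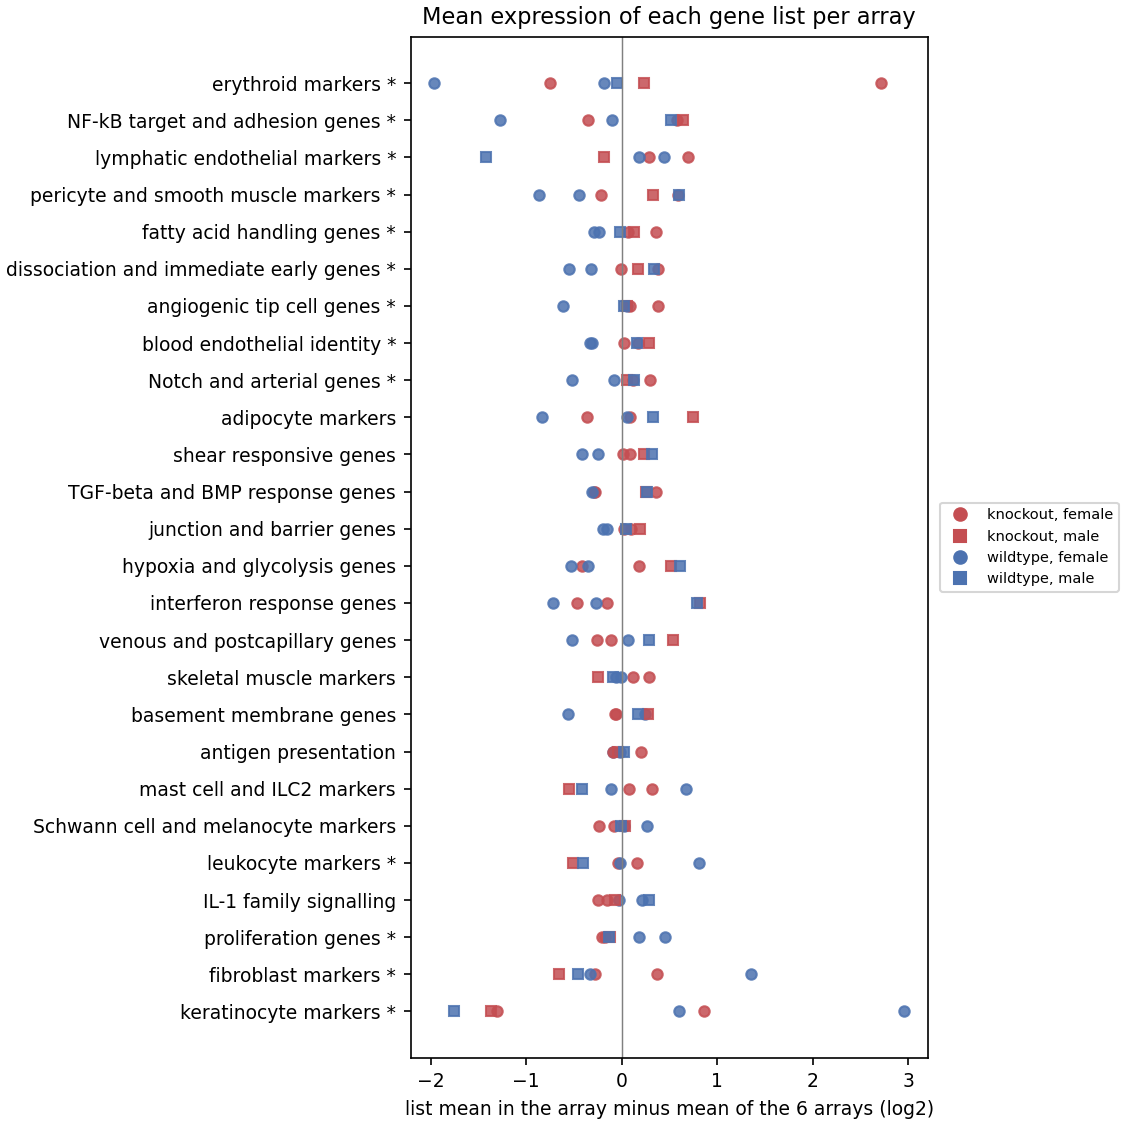
Mean log2 expression of each gene list in each array minus the mean of the 6 arrays (horizontal axis), with knockout arrays in red, wildtype arrays in blue, females as circles and males as squares; a star marks lists called by camera with the preset correlation. The keratinocyte mean spans 6.69 to 11.40 and the erythroid mean 6.87 to 11.54 across arrays.

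The other 13 lists did not pass either form of camera. In the list of IL-1 family signalling Il33 was called, alone among 17 tested members. The list mean was -0.32 and its median 0.16 (camera pointing down, adjusted p = 0.518). Myd88, the adaptor of these receptors, was 15.48 ± 0.41 against 14.65 ± 1.28, Irak3 differed by 0.21, and the receptor Il1rl1, at 4.08 against 3.84, lay low in both groups. Interferon response genes had a mean of 0.13 (camera adjusted p = 0.531), with Ifi27 differing by 0.22, Bst2 by 0.23 and Gbp2 by -0.35. Antigen presentation genes had a mean of 0.051 (camera adjusted p = 0.908), with B2m at the ceiling, Tapbp differing by 0.69 and RT1-A1 by 0.29. Junction and barrier genes had a mean of 0.21 (camera adjusted p = 0.120), with Cav1 differing by 0.13. Shear responsive genes had a mean of 0.23 (camera adjusted p = 0.395), with Timp3 at 14.31 ± 0.42 against 13.24 ± 0.56, Thbd differing by 0.80 and Klf4 by 0.63. TGF-beta and BMP response genes had a mean of 0.22 (camera adjusted p = 0.112), with Ccn1 differing by 0.36 and Acvrl1 by 0.29. Hypoxia and glycolysis genes had a mean of 0.19 (camera adjusted p = 0.399), with Gapdh differing by 0.63, Ldha by 0.50 and Ndrg1 by -0.020.

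Venous and postcapillary genes had a mean of 0.11 (camera adjusted p = 0.953), and Il6st, Emcn and Lifr differed by -0.023, -0.023 and 0.023. Basement membrane genes had a mean of 0.10 and a median of -0.023 (camera pointing up, adjusted p = 0.933), with Sparc at the ceiling, Sparcl1 differing by 0.77 and Serpinh1 by -0.010. Mast cell and ILC2 markers, the cell types on which interleukin-33 acts, had a mean of -0.10 and a median of 0.12 (camera pointing down, adjusted p = 0.722). Of 11 members tested, 7 were higher and 4 lower in the knockout. The 3 of highest signal were among the lower: Gata3 differed by -1.27, Kit by -0.35 and Hpgds by -0.48. Gata3 was highest in wildtype 34 (12.25), the array with the highest keratinocyte median. The list median lay at the 22.0th to 28.6th percentile of all genes. Adipocyte markers had a mean of 0.31 (camera adjusted p = 0.287), with differences of 1.10 for Lpl, 0.083 for Cidea and 0.16 for Cfd. Schwann cell and melanocyte markers had a mean of -0.19 (camera adjusted p = 0.446), with differences of 0.50 for Ngfr, 0.15 for Sox10 and -0.80 for Erbb3. Skeletal muscle markers had a mean of 0.11 (camera adjusted p = 0.590), with differences of -0.15 for Myh3, -0.097 for Ckm and 0.29 for Acta1. The list of Y-linked and X-inactivation genes had 2 members among the genes tested, too few for the test.

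Genes that neighbour Il33 were compared because a knockout founder can carry linked variants. Of 58 genes annotated within 2 Mb of Il33 in the RefSeq annotation of assembly GRCr8, 18 were tested; 9 were higher and 9 lower in the knockout, with a mean difference of 0.15 (camera p = 0.417, and p = 0.430 with an estimated correlation). None passed the limma test over all genes. The immune checkpoint ligand Cd274 was 13.65 ± 0.61 against 12.35 ± 1.56 and the kinase Jak2 11.85 ± 0.57 against 10.86 ± 0.79. Prkg1 differed by 0.85 and was the only neighbour at an unadjusted p under 0.05; these 3 genes were chosen after their values were seen.

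The female and male arrays differed more than the genotypes did, though both males also lay on the low side of spike-in signal. The Y-linked genes Ddx3y and Eif2s3y were higher in the males by at least 6.0 and 5.97 (limma adjusted p = 1.26e-04 for each), with means of 9.94 and 9.10 in the males against 3.94 and 3.12 in the females, which lie at or under the background probesets (medians of 4.55 to 4.73), in accord with the sex given for every animal. Ccl21 was lower in the males, with a difference of -4.49 (adjusted p = 0.0322), at 13.13 in knockout 52 and 9.91 in wildtype 37 against values from 15 to 17.06 in the females. Gnb4 (2.64), Lhfpl6 (2.66) and Pkhd1l1 (-2.46) had an adjusted p of 0.0654 each and did not pass. Of the 11 lymphatic markers tested, 6 lay lower in both males than in every female, namely Prox1, Pdpn, Flt4, Ccl21, Reln and Sema3d, and of these only Ccl21 passed. Gja1 (16 and 15.54 against at most 14.91) and Fgl2 (18.33 and 17.85 against at most 17.34) lay higher in both males than in every female, and the list as a whole was not tested for sex. Reln was 6.96 and 5.41 in the males against 8.55 to 8.90 in the females. In all, 3 genes passed and 2148 had an unadjusted p under 0.05; without knockout 27, 66 genes passed, and all 8 spike-in controls were lower in both males than in every female.

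**Figure D5:**
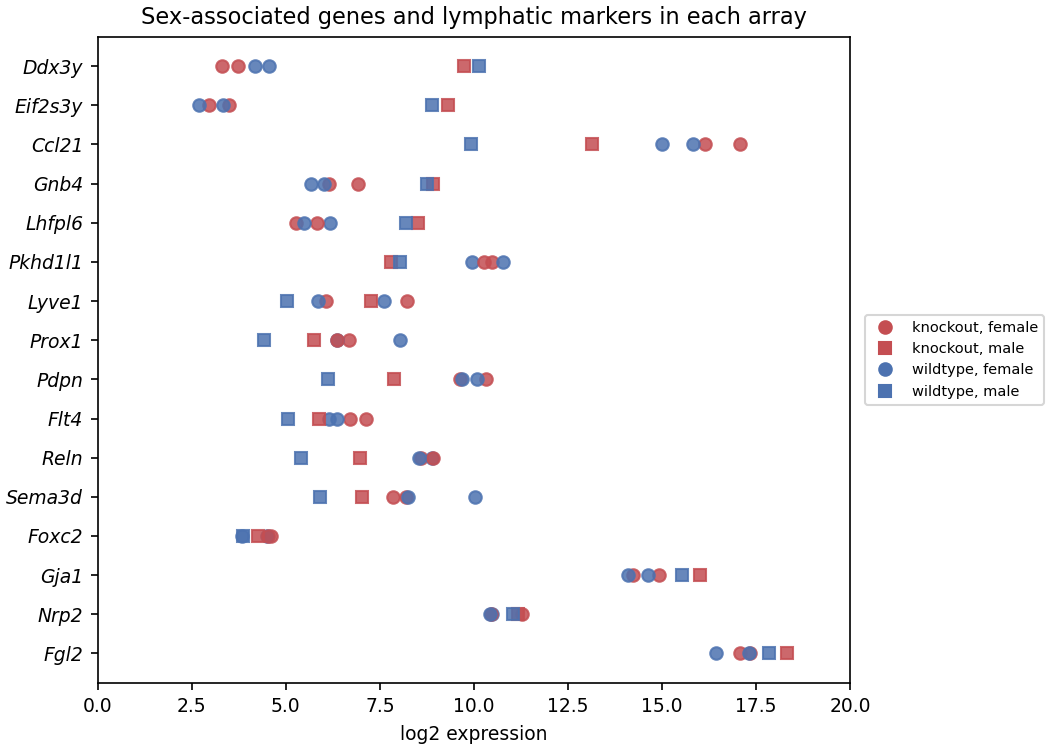
Log2 expression in each array (horizontal axis) of the 6 genes with the smallest p for sex and of the 11 lymphatic markers tested, Ccl21 being in both, with knockout arrays in red, wildtype arrays in blue, females as circles and males as squares. Ddx3y lies at 9.74 and 10.14 in the males and at 3.31 to 4.54 in the females.

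Whether the knockout effect differed between the sexes was tested with an interaction term. None of the genes passed (limma; smallest adjusted p = 0.999), and 119 had an unadjusted p under 0.05. For Il33 the difference was -6.87 in females and -6.78 in males. With 1 male in each group the interaction rests on the spread among the females.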

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

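The comparison in this part was chosen after the values were seen, and nothing in it was planned. Of the 63 ERCC control probesets, which no comparison between the animals uses, 3 lay above every background probeset (at most 5.87) on every array. The brightest, ERCCmix2step35, was 12.60, 13.25 and 12.20 on arrays 28, 34 and 45 and 8.10, 7.47 and 7.95 on arrays 27, 52 and 37, ERCCmix2step23 was 9.02 to 9.50 against 7.25 to 7.98, and ERCCmix1step11 was 7.92 to 8.17 against 7.12 to 8.0.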

How the results depend on the processing

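Tests with the keratinocyte median, the spike-in mean and the spike-in block were chosen after the result was seen. The Il33 difference kept its direction under all 19 alternatives. It lost its call with no filter on dim genes (-6.84, adjusted p = 0.0854), a filter at the 50th percentile (-6.84, 0.0544), each probeset on its own (-6.84, 0.0778) and females only (-6.87, 0.131). Leaving out each array gave -7.71 to -6.34; the call was kept without wildtype 34 (adjusted p = 0.00193) and lost without knockout 28 (0.270), 27 (0.661) or 52 (0.0687) and wildtype 45 (0.653) or 37 (0.0773). The number of genes called was 0 in those same settings and with the unmoderated statistic (312 at an unadjusted p under 0.05), and 0 to 1 over the left-out arrays (111 to 967 at an unadjusted p under 0.05, highest without wildtype 37). By construction more genes were tested with no filter and with each probeset, and fewer arrays entered with females only or an array left out; for the others the cause was not tested. Of the 100 other named genes, 0 passed in any alternative run on them. The number of lists called was 0 with an estimated correlation and 0 with fry, 8 with the keratinocyte median as a covariate and 8 with the spike-in block. It was 7 to 12 over the left-out arrays, with 7 without knockout 28, wildtype 34 or wildtype 45. Over the left-out arrays the leukocyte mean was -0.53 to 0.082, the fibroblast mean -0.71 to 0.20, the keratinocyte mean -2.38 to -0.028 and the lymphatic mean -0.048 to 0.88. The highest of these for leukocytes, fibroblasts and keratinocytes came without wildtype 34, where camera turned to higher, and the lowest lymphatic mean, where camera turned to lower, without wildtype 37. Genes differing by sex numbered 27 with sex alone in the design and 2 to 66 over the left-out arrays, the 66 without knockout 27; leaving out a male leaves 1 male, taken to vary like the other animals. The neighbours of Il33 and the interaction stayed without a call in every alternative run. Genes near background or at the ceiling can hide differences.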

Other observations

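Chosen after the result was seen were the comparison of arrays by spike-in signal, the spike-in block, the keratinocyte median as a covariate, the separate counts of lists higher and lower in the knockout, the count of lists with an estimated correlation as a reading of co-movement, and both tests on lymphatic markers. Arrays 28, 34 and 45, of high spike-in signal, differed from arrays 27, 52 and 37 far more than the genotypes did: 208 genes passed in limma, 44 higher and 164 lower on the arrays of high signal. The 6 higher genes with the smallest p were Krt15 at 15.73 ± 1.83 against 9.50 ± 0.40 (adjusted p = 0.0103), Pkib differing by 2.52, Krt14 by 4.83, Ly6d by 2.86, Krt1 by 4.75 and Clca5 by 4.42. The lower genes included the interferon-induced chemokine Cxcl10 (10.42 ± 0.41 against 13.61 ± 0.51, adjusted p = 0.0103), the glucose transporter Slc2a3 (9.86 ± 0.97 against 13.60 ± 0.30) and the arginine transporter Slc7a2 (7.08 ± 0.66 against 10.30 ± 0.33). By camera the keratinocyte list was higher by a mean of 2.95 with 9 of 13 members called, and the fibroblast list by 0.93. The NF-kB, interferon, hypoxia and pericyte lists were lower, by means of -1.16, -0.97, -0.87 and -1.02. In all, 9 lists were called and 0 with an estimated correlation. These groups are sets of samples divided by a technical measure and not groups of the study.

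The 13 list differences between genotypes were weighed against RNA of other skin cells in wildtype animal 34, where Krt15 was 17.82, Krt1 17.14 and Dcn 16.33 although the sort retained CD31-positive cells. Of the members of the lower lists 9 of 13 (keratinocyte), 8 of 16 (fibroblast), 5 of 18 (leukocyte) and 6 of 22 (proliferation) lay above the median of the background probesets on every array, so the leukocyte and proliferation calls rest largely on genes near background. Without that animal 7 of the 13 lists stayed called, a count that decides nothing over the 13 together. All 7 were among the 9 higher lists (the erythroid list at 1.74). In the erythroid, lymphatic, Notch and tip cell lists animal 34 lay above the wildtype mean. Leaving it out thus had to widen their differences, so their kept calls decide nothing, though animal 34 did not lower the wildtype mean there. The pericyte, immediate early and fatty acid means shrank to 0.36, 0.29 and 0.31 and stayed called. That argues against such RNA in animal 34 alone as the whole source of those calls at the preset correlation. None of this tests such RNA in other animals. Without wildtype 45 the Notch, tip cell, pericyte, immediate early and fatty acid calls were lost, and the erythroid and lymphatic calls kept. The higher NF-kB (mean 0.082, camera adjusted p = 0.514) and blood endothelial (0.23, 0.0620) lists lost their calls without animal 34. The loss of all 4 lower calls decides nothing, since animal 34 had the highest mean of each. Its absence must pull them toward 0, so their source stays open. With the keratinocyte median as a covariate the fibroblast and leukocyte calls (camera adjusted p = 0.694 for each) were lost. Those of the higher NF-kB (0.0803) and pericyte (0.129) lists were lost too, and the blood endothelial list stayed called (0.0196). RNA of other skin cells in several animals thus stays open for the lists lost, the pericyte list included. The proliferation list stayed called (0.0393) with a difference of -0.23 (SE 0.075, 95% interval -0.47 to 0.0077), which leaves keratinocyte RNA as its source open. With an estimated correlation 0 of the 13 stayed called, which members moving together from animal to animal could give. That form of camera, however, called 0 lists in each of the 10 splits of the arrays. These include the split by spike-in signal, where 9 of 13 keratinocyte members were called singly. Its 0 thus cannot tell co-movement from a shift, and whether co-movement gave these calls stays open. Besides, 3 against 3 allows too few splits for a share under 0.05 (1 of 10 reached the real 13 lists, the highest other 11).

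Fewer genes (227) had an unadjusted p under 0.05 than the 576 that make 5% of those tested, and whether wildtype animal 34 widened the spread stays open, since the 147 without it come from fewer arrays and leaving out another array gave 111 to 967. The split between female and male arrays and the split by spike-in signal may each add to the spread within genotypes, since 473 genes were reached with sex as a covariate and 320 with the spike-in block, both short of 576; they cannot be told apart, since both males lie on the low side. Counts of 620 with females only and 967 without wildtype 37 do not measure this, since both leave only wildtype 34 and 45, of high spike-in signal, against knockouts of high and low signal. For the number of genes called, 3 against 3 allows too few splits for a share under 0.05: 2 of the 10 splits called at least the real 1 gene. The highest other, 208, is the split of arrays by spike-in signal and points to a structure of the samples; with that split as a block, Il33 was the 1 gene called between genotypes (adjusted p = 0.00436, within a range of 1.98e-04 to 0.661 over its alternatives).

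Of 11 lymphatic markers tested, 6 were lower in both of the 2 males than in every female, with Ccl21 alone passing the test, while Gja1 and Fgl2 were higher in both. Fewer lymphatic cells left after the sort in the male preparations is a candidate explanation, which the count of 6 allows. Array handling that differed between the male and the female arrays stays open too, since all 8 spike-in controls lay below the female range in both males. Sex, sort and handling cannot be told apart with 2 male arrays, and a sex difference in these cells stays open as untested.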
